A study of Homo sapiens with 24 samples.

How the data were processed

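RNA from THLE-2 cells, a human hepatocyte line immortalised with the SV40 large T antigen, was sequenced after retroviral transduction with an empty vector or with NICD1, the intracellular and constitutively active part of the NOTCH1 receptor. Each of the 2 groups had 3 replicates, and each replicate was listed as 4 numbered parts, which made 24 samples. The authors deposited raw read counts per Ensembl gene for 63677 genes, without normalisation. The submitters' processing notes name bcl2fastq, STAR 2.5.0a, Picard and HTSeq with the hg38 build. The gene annotation version and the strand setting of the counting are not given in the sources used here. Without a known strand setting, reads of overlapping genes on opposite strands cannot be told apart. The labels' protocols describe the control once as empty vector and once as GFP, and it is called empty vector here.

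Part 4 held the same count as part 3 for every gene in all 6 replicates. The identical parts were counted once, and each replicate was the sum of its 3 distinct parts, where a sum of all 4 parts had been planned. The distinct parts of a replicate differed by a chi-square of 1.03 to 1.04 per degree of freedom over genes with at least 30 counts, close to counting noise. Replicates differed by 5.96 in the empty vector group and 13.8 in the NICD1 group. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Replicate totals ran from 10617007 to 12821140 counts, and 3 counts in a replicate corresponded to 0.234 to 0.283 CPM (counts scaled to the library total). Intervals and such floors cover counting error only.

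Genes were named as in the deposited table and placed on the genome with GENCODE 29, which held 52526 (82.5%) of the gene IDs. The other IDs took 0.65% of the counts. Genes were tested with edgeR 4.0.16 in R 4.3.3, using its quasi-likelihood test with robust dispersion, TMM scaling, its default filter on low counts and Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05, and 14445 genes passed the filter. Log2 fold changes are NICD1 against empty vector, and their standard errors (SE) were approximated from the fold change and the F statistic. Values per gene are TMM-scaled CPM with the SD over 3 replicates. For genes with at most 10 counts in the empty vector group, the ratio of pooled counts is given with an exact 95% interval.

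The groups, the tests, the alternative settings, the 27 gene lists and the rule for named genes were fixed before the data were examined. The sum of 3 distinct parts was not, since it replaced the planned sum of 4 once the identical parts were seen. The rule took NOTCH1, then the 12 largest rises and the 12 largest falls among called genes with a symbol, a mean of at least 2 CPM and no overlap between the groups. For each list it took up to 2 rising and 2 falling called members, or the 2 most abundant members where none was called, and all tested Notch targets. Genes named outside it are said to be chosen after their values were seen. Lists with at least 5 tested members were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01. An estimated correlation per list and fry, which asks whether a list's members move in a common direction, were run beside it.

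On simulated counts with the real means and library sizes, the test called 62.8% of genes changed 1.5-fold, 82% of those changed 2-fold and 98.8% of those changed 4-fold. It called 53 of 71125 unchanged genes. Each simulated gene took the dispersion typical of its expression level, and no simulated replicate stood apart. These rates may therefore not hold for the real genes, whose calls depended on single replicates. The list test called 5 of 5 shifted lists and 0 of 130 unshifted lists. Simulated genes varied independently, whereas the correlation estimated in the real lists reached 0.678 for interferon-stimulated genes. The simulation therefore does not give the rate of false calls for lists whose members move together. Alternatives were DESeq2 1.42.0, limma-voom, other scalings, other filters on low counts, the replicate number as a block, each replicate left out, part 1 alone, and all 24 parts as samples with and without a random effect of the replicate. The planned sum of all 4 parts was made an alternative after the data were seen. Summaries were made in Python 3.11.15 with pandas 2.3.3 and scipy 1.17.1.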

Results

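Transcriptomes of THLE-2 hepatocytes carrying an empty retroviral vector or NICD1 were compared to ask what the active NOTCH1 intracellular domain changes in these cells. There were 3 replicates per group. The empty vector replicates held 10617007, 12100317 and 11747972 counts, and the NICD1 replicates 12821140, 12035729 and 11488069. On the first principal component, which held 50.1% of the variance, NICD1 replicates 1 and 2 lay at 23.28 and 40.05 and NICD1 replicate 3 at -8.12. The empty vector replicates lay at -20.93, -7.17 and -27.11.

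**Figure D1:**
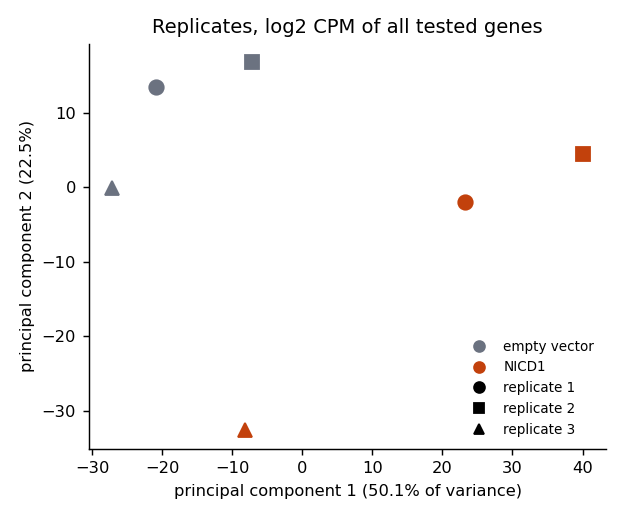
Position of the 6 replicates on the first and second principal components of log2 CPM over all tested genes, with colour for the group and symbol for the replicate number. NICD1 replicate 3 lies at -8.12 on the first component, between empty vector replicates, and at -32.59 on the second.

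NOTCH1 (chromosome 9, 136494433 to 136545786, hg38) was higher in every NICD1 replicate than in every empty vector replicate. It stood at 34.9 ± 4.23 CPM (SD, n = 3) with empty vector and at 963 ± 823 CPM (SD, n = 3) with NICD1. The NICD1 replicates differed among themselves, at 602.6, 381.2 and 1905 CPM, so that replicate 3 held 3.16 times the level of replicate 1 and 5.00 times that of replicate 2. The log2 fold change was 4.79 (SE 0.75), with an adjusted p of 0.074, which did not pass the threshold. Without NICD1 replicate 3 it was 3.81 with an adjusted p of 0.00153. DESeq2 and limma-voom on all replicates gave adjusted p of 1.67e-08 and 0.017. Over all alternatives the adjusted p ran from 1.53e-09 to 0.269. The lowest came from the 24 parts as separate samples, a fit that counts repeat measurements as replicates. The exact two-sided permutation p was 0.1, the smallest that 3 against 3 replicates allow. Counts assigned to NOTCH1 cannot separate the introduced sequence from the cell's own gene.

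Of 14 tested Notch target genes edgeR called 2 higher, HEYL and HES1, transcriptional repressors switched on by Notch. The list passed camera as higher (adjusted p = 2.73e-05; adjusted p = 0.185 with an estimated correlation). HEYL rose from 1.18 ± 0.279 to 8.14 ± 3.73 CPM (SD, n = 3), a log2 fold change of 2.76 (SE 0.41, adjusted p = 0.0223). HES1 rose from 10.04 ± 0.351 to 24.9 ± 6.86 CPM, a log2 fold change of 1.31 (SE 0.19, adjusted p = 0.0193). The other 12 did not pass. Of all 14, 11 lay above 0, 6 were higher when adjusted over the list alone, 8 had an unadjusted p under 0.05 and DESeq2 called 5 higher and 0 lower. With all replicates limma-voom called only 1 target, HES1, so HEYL did not pass there. Among those that did not pass, HES4 had a log2 fold change of 1.34 (adjusted p = 0.135), SOX9 1.19 (adjusted p = 0.125), HEY1 1.0 (adjusted p = 0.279), NOTCH3 0.94 (adjusted p = 0.139) and NRARP 0.60 (adjusted p = 0.0842). Without NICD1 replicate 3 edgeR called 5 targets higher and 1 lower. HES4 was then at 0.85 (adjusted p = 0.026) and HEY1 at 0.38, and HES4 also passed without NICD1 replicate 2 (adjusted p = 0.0418). CD44, CCND1, JAG1 and HES2 lay between 0.05 and 0.17, and BHLHE41, MYC and HES7 at -0.03, -0.21 and -0.39. HES5 and HEY2 had at most 4 counts in any replicate and DTX1 at most 15, and they were not tested. HEYL and HES1 did not pass when any empty vector replicate or NICD1 replicate 1 was left out, with adjusted p of 0.16 and 0.146 without empty vector replicate 1, the highest over all alternatives. The 37 tested components of the pathway held 0 called genes by edgeR, 2 at an unadjusted p under 0.05 and 2 called by DESeq2. Among them NOTCH2 was at -0.03. Their median was 0.01, their mean lay below 0 and camera pointed down (adjusted p = 0.868).

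**Figure D2:**
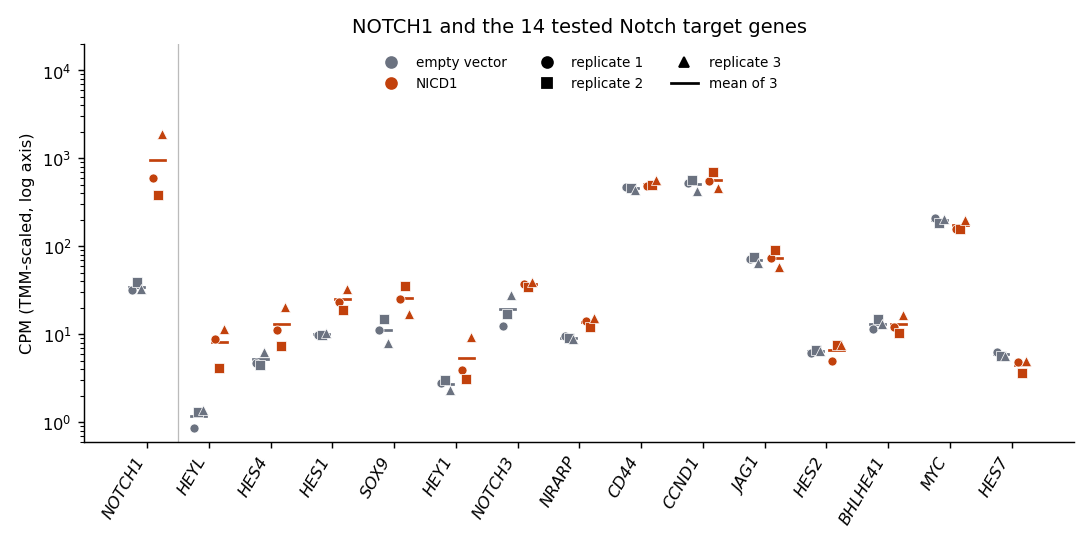
CPM on a log axis for NOTCH1 and the 14 tested Notch targets in each of the 6 replicates, with a short line at the mean of 3. NOTCH1 reached 1905 CPM in NICD1 replicate 3, and HEYL and HES1 are the targets whose rise passed the test.

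Across the transcriptome, 81 genes rose and 53 fell among 14445 tested, and 43 of the rises and 16 of the falls were at least 2-fold. Of the 134 called genes 130 were protein coding, and the median size of their log2 fold change was 0.93. All 134 had no overlap between the groups, as did 21.8% of all tested genes. The 10% that chance gives is an average over the 10 ways to split the replicates 3 against 3. Genes that vary together can exceed it in a single split, and the share in the other splits was not computed. The excess is therefore no evidence of a group effect. The largest rise was in IGFBP5, which binds insulin-like growth factors (chromosome 2, 216672105 to 216695525), with 10 counts in the empty vector group and 660 in the NICD1 group. The ratio was 62.6 (95% interval 33.8 to 131), with a log2 fold change of 5.90 (SE 0.53, adjusted p = 0.00563). IGFL1 had 6 and 340 counts, a ratio of 53.7 (95% interval 24.4 to 147) and an adjusted p of 0.0153. ADAMTS5, a protease that cleaves aggrecan, rose by a log2 fold change of 3.28 (SE 0.35, adjusted p = 0.00632), and KCNG1, a potassium channel subunit, from 3.94 ± 0.793 to 25.6 ± 5.1 CPM (log2 fold change 2.69, adjusted p = 0.00265). ROBO1, the receptor of SLIT guidance cues, rose by 2.31, the transcription factor MSC by 2.27, the long noncoding RNA AC112721.2 by 2.19, RSPO4, a secreted enhancer of WNT signalling, by 2.18 and the junction protein JAM3 by 2.11 on the log2 scale. None of these rises passed without empty vector replicate 1.

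Among called genes with a mean of at least 2 CPM, the largest falls were in HLA-DRB5, an HLA class II chain, and in ESAM, an adhesion molecule of tight junctions. HLA-DRB5 went from 6.84 ± 4.1 to 0.921 ± 0.340 CPM, a log2 fold change of -2.86 (adjusted p = 0.0417), and its reads are uncertain because HLA-DRB1 is nearly identical. ESAM went from 30.1 ± 5.76 to 7.34 ± 1.22 CPM, a log2 fold change of -2.03 (SE 0.18, adjusted p = 0.00552). The potassium channel subunit KCNAB2 fell from 25.8 ± 0.890 to 9.70 ± 0.569 CPM (log2 fold change -1.41, adjusted p = 0.00265), and WNT7B, a WNT ligand, from 39.4 ± 7.75 to 12.3 ± 2.68 CPM (-1.67, adjusted p = 0.0108). C4orf19 fell by 1.84, the TNF receptor TNFRSF1B by 1.70, CPT1C by 1.5, the carboxypeptidase CPA4 by 1.22, ADAMTSL1 by 1.21, SDPR (also called CAVIN2), a protein of caveolae, by 1.2, the tubulin TUBB4A by 1.19 and SLC22A23 by 1.12 on the log2 scale. Exons of IGFBP5, IGFL1, KCNG1, MSC, JAM3, C4orf19, KCNAB2, SDPR, TUBB4A and SLC22A23 overlap a gene on the opposite strand, so their counts may include its reads. None of the falls passed without empty vector replicate 1.

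The number of called genes depended on single replicates. In place of 134 genes, edgeR called 0 without empty vector replicate 1, where 1530 genes were at an unadjusted p under 0.05. It called 28 genes without empty vector replicate 2, 55 without empty vector replicate 3, 19 without NICD1 replicate 1, 106 without NICD1 replicate 2 (90 of them shared) and 2107 without NICD1 replicate 3, which included all 134. DESeq2 called 485 genes with all replicates, 133 of them shared, and limma-voom 124, 117 of them shared. In the Notch pathway, epithelial, proliferation, p53, MAPK, antigen presentation, interferon-stimulated, hypoxia, ribosomal and neuronal lists, limma-voom called 0 genes, as did edgeR. The members that DESeq2 called in these lists therefore rest on that method.

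Of 47 tested extracellular matrix genes edgeR called 6 higher and 0 lower, with 20 at an unadjusted p under 0.05. DESeq2 called 10 higher and 2 lower, and edgeR without NICD1 replicate 3 called 12 higher and 6 lower. COL12A1 rose from 18.4 ± 6.06 to 108 ± 40.8 CPM (SD, n = 3), a log2 fold change of 2.56 (SE 0.38, adjusted p = 0.0454), and periostin (POSTN) from 21.5 ± 2.97 to 111 ± 43.6 CPM, a log2 fold change of 2.37 (adjusted p = 0.0351). The collagen VI chains COL6A3 and COL6A1 rose by 1.77 and 1.72, the matricellular protein THBS1 by 0.77 and the crosslinking enzyme LOXL2 by 0.43; these were named after their values were seen. COL6A2 had a log2 fold change of 3.73 (adjusted p = 0.121), COL1A1 of -0.08 and COL17A1 of -1.87 (adjusted p = 0.101), also chosen after their values were seen. Adjusted over the list alone, 12 were higher and 3 lower. Camera gave an adjusted p of 2.73e-05 (adjusted p = 0.202 with an estimated correlation). COL12A1 and POSTN did not pass when any replicate other than NICD1 replicate 3 was left out, with adjusted p of 0.18 and 0.165 without empty vector replicate 1, the highest over all alternatives. Among 29 mesenchymal genes TAGLN, an actin-binding protein of smooth muscle, rose by 0.98 (adjusted p = 0.0105, and 0.0986 without empty vector replicate 1), and 3 were higher adjusted over the list alone. That list passed camera (adjusted p = 0.00224; adjusted p = 0.328 with an estimated correlation) but not without NICD1 replicate 3 (adjusted p = 0.175). Its median was 0.11, and ran from 0.10 to 0.22 over all alternatives.

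The hepatocyte, epithelial and biliary lists passed camera as lower, with 1, 0 and 1 members called by edgeR. With an estimated correlation none of them passed (adjusted p = 0.148, 0.328 and 0.465). Of 42 hepatocyte markers 12 were expressed enough to test, and albumin (ALB) had at most 1 count in a replicate. FOXA1, a liver transcription factor, fell from 14.1 ± 0.954 to 7.45 ± 0.659 CPM (log2 fold change -0.92, SE 0.14, adjusted p = 0.0186), with 4 markers lower adjusted over the list alone. The fibrinogen chains FGG and FGA, chosen after their values were seen, were at -1.88 and -2.61 (adjusted p = 0.0605 and 0.0708). The hepatocyte list had a median of -0.62 (adjusted p = 1.12e-04; adjusted p = 0.148 with an estimated correlation). That median was -0.37 without empty vector replicate 3, -0.39 without NICD1 replicate 1 and -0.29 without NICD1 replicate 2, and over all alternatives it ran from -0.87 with part 1 alone to -0.08 with no filter on low counts. Of 23 epithelial genes 0 were called by edgeR, 6 had an unadjusted p under 0.05 and DESeq2 called 2, with 2 lower adjusted over the list alone. LAMB3 was at -0.18 and KRT8 at -0.01, and the list had an adjusted p of 0.00309 (adjusted p = 0.328 with an estimated correlation). Of 17 biliary markers BICC1, an RNA-binding protein, fell by 0.47 on the log2 scale (adjusted p = 0.0399), with 1 higher and 3 lower adjusted over the list alone. The biliary list (adjusted p = 0.0478; adjusted p = 0.465 with an estimated correlation) did not pass when any replicate other than empty vector replicate 1 was left out. Its adjusted p was 0.0537 and 0.215 without empty vector replicates 2 and 3, and 0.176, 0.0588 and 0.0572 without NICD1 replicates 1, 2 and 3. FOXA1 and BICC1 did not pass when any empty vector replicate or NICD1 replicate 1 was left out, nor BICC1 without NICD1 replicate 2, with adjusted p of 0.119 and 0.197 without empty vector replicate 1.

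Among sterol and fatty acid synthesis genes edgeR called 2 of 24 and 1 of 19 higher. Both lists passed camera as higher, but neither passed with an estimated correlation (adjusted p = 0.112 and 0.185 with an estimated correlation). HMGCS1, an early enzyme of cholesterol synthesis, rose from 58.3 ± 0.712 to 103 ± 3.59 CPM (log2 fold change 0.83, SE 0.07, adjusted p = 0.00265). Of the cholesterol genes 7 were higher adjusted over the list alone and 20 lay above 0, with a median of 0.21 (adjusted p = 5.03e-07). SCD, which desaturates fatty acids, rose by 0.51 (adjusted p = 0.0109), the only fatty acid gene called by edgeR, where DESeq2 called 3 higher and 1 lower. Adjusted over the list alone 4 fatty acid genes were higher and 1 lower (adjusted p = 0.00714 for the list). HMGCS1 and SCD had adjusted p of 0.067 and 0.104 without empty vector replicate 1.

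Growth and stress genes showed few single calls. Of 44 proliferation genes 0 were called by edgeR, 12 had an unadjusted p under 0.05 and DESeq2 called 2, with 0 adjusted over the list alone and 36 below 0. TOP2A was at -0.27 and MKI67 at -0.19, and the list had an adjusted p of 8.19e-05 (adjusted p = 0.493 with an estimated correlation). Of 30 p53 targets 0 were called, 13 had an unadjusted p under 0.05, DESeq2 called 3 and 3 were higher adjusted over the list alone. The p53 list had a median of 0.22, with CDKN1A at 0.32 and TNFRSF10B at 0.18 (adjusted p = 3.83e-06; adjusted p = 0.328 with an estimated correlation). Cyclin D2 (CCND2) rose from 2.08 ± 0.336 to 7.05 ± 2.57 CPM (log2 fold change 1.75, adjusted p = 0.0343), among 14 kinase regulators of which 2 were higher and 2 lower adjusted over the list alone (adjusted p = 0.139). Of 23 MAPK feedback genes 0 were called, 9 had an unadjusted p under 0.05 and DESeq2 called 4, with 5 higher and 1 lower adjusted over the list alone. IER3 was at 0.25, and the list had an adjusted p of 0.0152 (adjusted p = 0.185 with an estimated correlation). CCND2 had an adjusted p of 0.192 without empty vector replicate 1 and passed in 11 of 17 alternatives. It was not called by limma-voom with all replicates.

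Inflammatory genes included calls in both directions, and their list passed camera as lower (adjusted p = 0.00224; adjusted p = 0.629 with an estimated correlation). The cytokine LIF rose by 0.54 (adjusted p = 0.018) and BIRC3, an NF-kB feedback gene, fell from 344 ± 4.56 to 210 ± 33.6 CPM (log2 fold change -0.71, adjusted p = 0.0198), among 34 tested. Adjusted over the list alone 2 were higher and 2 lower. Without NICD1 replicate 3, 2 were called higher and 18 lower over all genes, and the list was lower with an adjusted p of 1.29e-18. The list had a median of -0.29, which was -0.15 without NICD1 replicate 2 and -0.56 without NICD1 replicate 3, and an adjusted p of 0.155 without NICD1 replicate 2. LIF and BIRC3 had adjusted p of 0.146 and 0.145 without empty vector replicate 1. Of 23 antigen presentation genes 0 were called, 10 had an unadjusted p under 0.05 and DESeq2 called 1 higher and 6 lower. Adjusted over the list alone 1 was higher and 6 lower, with B2M at 0.06. Its median was 0.06, its mean -0.36 and camera pointed down (adjusted p = 0.209). It passed as lower in 4 of 18 alternatives, among them without empty vector replicate 1 (adjusted p = 0.0242) and empty vector replicate 2 (0.00431), with adjusted p from 0.00217 to 0.862. Of 40 interferon-stimulated genes 0 were called, 3 had an unadjusted p under 0.05 and DESeq2 called 3, with 1 higher and 1 lower adjusted over the list alone. IFITM3 was at -0.19, and the median was -0.05, the mean 0.02 and camera pointed down (adjusted p = 0.868). That list was higher without empty vector replicate 2 (median 0.26, adjusted p = 0.0331) and lower without NICD1 replicate 1 (median -0.25, adjusted p = 0.0177) or empty vector replicate 1 (median -0.20, adjusted p = 0.00278).

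Several other lists held 0 called genes by edgeR. Hypoxia genes had 3 higher adjusted over the list alone, with LDHA at -0.11 and PGK1 at -0.13 (27 tested, 4 at an unadjusted p under 0.05, 3 called by DESeq2, adjusted p = 0.0532). That list passed as higher in 8 of 18 alternatives, among them without empty vector replicate 3 (adjusted p = 1.63e-08), NICD1 replicate 1 (0.032) and NICD1 replicate 2 (0.0473), and its median ran from 0.03 to 0.26 and its adjusted p up to 0.789. Stem and progenitor markers had 3 lower adjusted over the list alone, with ALCAM at -0.50 (11 tested, 6 at an unadjusted p under 0.05, 3 called by DESeq2, adjusted p = 0.0532). That list passed in 6 of 18 alternatives, with an adjusted p from 0.00946 to 0.294 (0.0427 without NICD1 replicate 2) and a median from -0.29 to 0.09, above 0 only without NICD1 replicate 3. The other 5 lists of this kind had 0 adjusted over the list alone. Unfolded protein response genes, with HSP90B1 and CALR at 0.00, had 1 of 21 at an unadjusted p under 0.05 and 0 called by DESeq2 (adjusted p = 0.533, and 0.0473 without NICD1 replicate 2). Amino acid starvation genes, with SLC7A5 at 0.24 and STC2 at 0.19, had 3 of 24 and 0 by DESeq2, and a median of -0.02 against a mean of 0.01 (camera up, adjusted p = 0.868). YAP targets, with ANKRD1 at 0.39 and CYR61 at -0.12, had 3 of 23 and 0 by DESeq2 (adjusted p = 0.659). Ribosomal proteins, with RPL4 at -0.15 and RPL7A at 0.03, had 11 of 57 and 2 by DESeq2. They were lower as a list (adjusted p = 0.0142; adjusted p = 0.515 with an estimated correlation), but not without NICD1 replicate 3 (adjusted p = 0.171). Mitochondrial transcripts, with MT-CO1 at 0.06 and MT-ND4 at 0.08, had 4 of 13 and 0 by DESeq2. They were higher as a list (adjusted p = 0.0152; adjusted p = 0.568 with an estimated correlation), but not without empty vector replicate 2 (adjusted p = 0.0801), empty vector replicate 3 (0.0961) or NICD1 replicate 1 (0.0966).

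Markers of other liver cell types were mostly at low levels. Among 18 endothelial markers 10 were tested, of which FLT1, a VEGF receptor, rose and ESAM fell, with 1 higher and 1 lower adjusted over the list alone. FLT1 had 3 counts in the empty vector group, all in replicate 2, and 120 in the NICD1 group, a ratio of 37.9 (95% interval 12.7 to 187; adjusted p = 0.0109, and 0.0986 without empty vector replicate 1). Its log2 fold change was 5.09, and 8.28 without empty vector replicate 2, which leaves no counts in that group, so that the prior count sets the value. The endothelial median was -0.30, the mean 0.06 and camera pointed down (adjusted p = 0.258). Without NICD1 replicate 3 that list passed as lower (adjusted p = 0.0199, median -0.42), with 1 called higher and 5 lower, and its adjusted p ran from 0.00111 to 0.465 over all alternatives. Among stellate cell and fibroblast markers 10 of 18 were tested, and 4 of the 18 are also in the matrix list. Cytoglobin (CYGB) rose from 119 ± 5.43 to 213 ± 18.8 CPM (log2 fold change 0.83, adjusted p = 0.00563, and 0.0721 without empty vector replicate 1), with 2 higher adjusted over the list alone. That list had a median of 0.50 (adjusted p = 0.00326; adjusted p = 0.185 with an estimated correlation) and adjusted p of 0.124 without NICD1 replicate 3 and 0.102 without empty vector replicate 1, and with no filter on low counts a median of 0.17 (adjusted p = 0.231). Of 20 immune cell markers 4 were tested and 0 called by edgeR or DESeq2, with 2 at an unadjusted p under 0.05, 0 adjusted over the list alone, CD14 at 0.34 and CSF1R at 0.43. Of 7 tested neuronal markers 0 were called by edgeR, 3 had an unadjusted p under 0.05 and DESeq2 called 1. None passed adjusted over the list alone, ENO2 was at 0.10 and UCHL1 at -0.99, and the median was 0.10 against a mean of -0.09 (camera down, adjusted p = 0.659).

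In all, camera called 9 lists higher and 6 lower of 26 tested. Splitting the 6 replicates 3 against 3 in other ways, which mix the groups, called 5 to 15 lists. A camera call at the preset correlation is therefore weak support. With an estimated correlation camera called 0, with 6 at an unadjusted p under 0.05, and fry called 6. Those were the hepatocyte list as lower and the Notch target, cholesterol, fatty acid, MAPK and stellate cell lists as higher. Their fry adjusted p ran from 0.00204 (fatty acid) to 0.0386 (Notch targets). The other lists that camera called did not pass fry, the lowest being matrix genes (adjusted p = 0.0934).

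**Figure D3:**
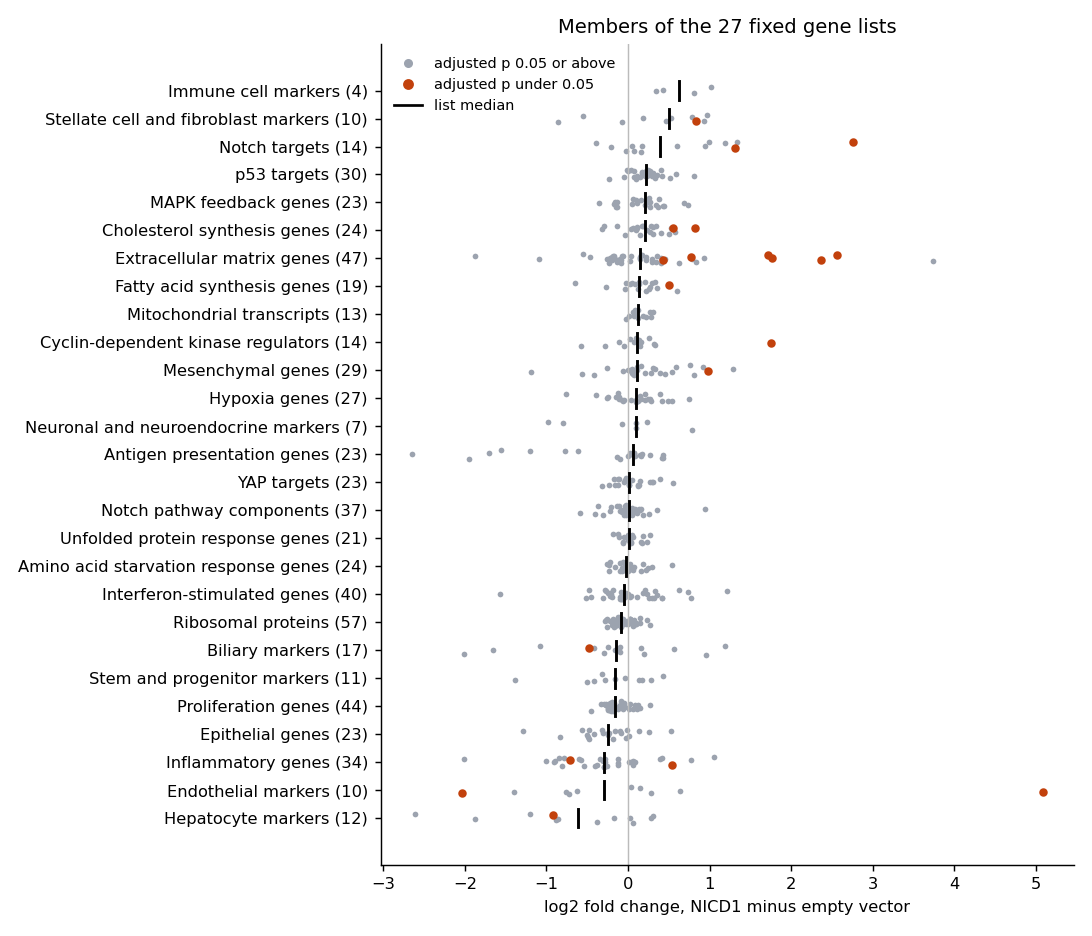
Log2 fold change of each tested member of the 27 lists, NICD1 against empty vector, with the number tested in brackets, a black line at the list median and coloured points for genes with an adjusted p under 0.05. Matrix genes hold the most called members, 6 of 47.

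**Figure D4:**
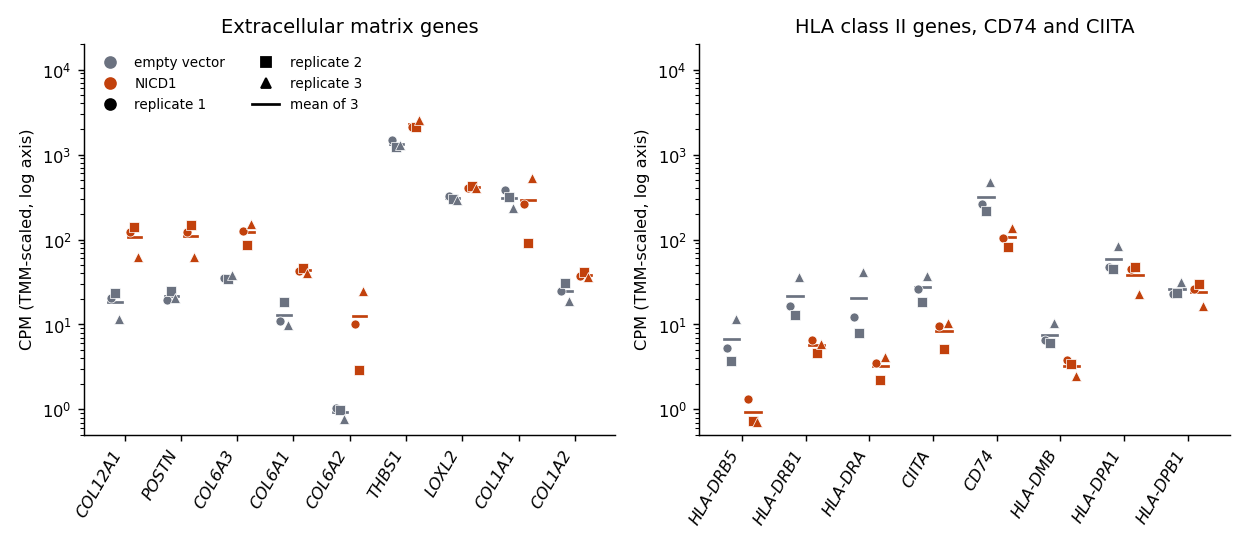
CPM on a log axis of matrix genes (left) and of HLA class II genes with CD74 and CIITA (right) in each replicate, with a short line at the mean of 3. COL12A1 and POSTN are higher in all 3 NICD1 replicates, and HLA-DRB5 is lower in all 3.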

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

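The main sum of 3 distinct parts was chosen after seeing the data, and the planned sum of all 4 parts then became an alternative. All tested genes among the 134 kept their direction under all 17 alternative fits. None of the 134 overlapped between the groups, so this follows largely from how they were selected and is no separate support. Genes higher and lower numbered 265 and 220 with DESeq2 (101 and 54 at least 2-fold), 603 and 586 with no filter on low counts (218 and 102), 2386 and 2292 with the 24 parts as separate samples (114 and 63) and 661 and 777 with the replicate as a random effect (90 and 81). Treating parts as samples counts repeat measurements as replicates, and both fits on 24 parts also hold part 3 and its identical part 4. With single replicates left out, genes higher ran from 0 (without empty vector replicate 1, 1530 genes at an unadjusted p under 0.05) to 970 (without NICD1 replicate 3), genes lower from 0 to 1137, and those at least 2-fold from 0 to 265 and from 0 to 170. For these counts the cause was not tested. The sum of all 4 parts called 139 genes, 123 of them shared. Same-numbered replicates correlated at 0.02, 0.39 and 0.33 in their deviations from the group means. Replicates 2 and 3 correlated best with their own number, and replicate 1 did not. With so few replicates this check cannot decide, so whether the numbers pair the samples stays open. A replicate block gave 405 higher and 359 lower (135 and 72 at least 2-fold), with 134 of 134 calls kept. NOTCH1 had a log2 fold change of 4.79 with DESeq2, 4.44 with limma-voom, 4.78 with 24 parts and 4.42 with the random effect, all past the threshold, and 3.81 (without NICD1 replicate 3) to 5.17 (without NICD1 replicate 2) with replicates left out. Lists called higher and lower numbered 0 and 0 with an estimated correlation and 5 and 1 with fry. The interferon-stimulated list reversed to a median of 0.26 without empty vector replicate 2 (adjusted p = 0.0331, range over alternatives 0.00278 to 0.969), and its medians with single replicates left out ran from -0.25 to 0.26; the cause was not tested. Depth limits genes near 3 counts per replicate, such as HES5 and HEY2.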

Other observations

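Called genes outside the lists are given here one by one, all chosen after their values were seen and tested for no common theme. The hyaluronan synthase HAS2 rose from 10.7 ± 1.45 to 27.1 ± 7.80 CPM (SD, n = 3; log2 fold change 1.34, adjusted p = 0.0277), and KIAA1199, which takes part in hyaluronan breakdown, from 3.53 ± 0.610 to 14.2 ± 3.00 CPM (2.01, adjusted p = 0.00632). INHBA, which encodes a subunit of activin, rose from 81.5 ± 15.0 to 196 ± 27.6 CPM (1.27, adjusted p = 0.0109), the protease-activated receptor F2RL1 by 1.13 and the cytokine IL24 by 1.35 on the log2 scale. Among genes that fell were the hyaluronan receptor HMMR (-0.48, adjusted p = 0.0408), the hepatocyte growth factor receptor MET, from 223 ± 16.3 to 153 ± 3.89 CPM (-0.55, adjusted p = 0.0148), the TGF-beta receptor TGFBR2 (-0.43, adjusted p = 0.0225), the protease inhibitor SPINT2 (-0.97, adjusted p = 0.0155) and the epithelial transcription factor EHF (-0.58, adjusted p = 0.00949). As with all calls, edgeR called 0 of these without empty vector replicate 1, where 1530 genes were at an unadjusted p under 0.05.

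Among the tests that follow, those on admixture, on the amount of NICD1 transcript, on fibroblasts, on immune cells and on HLA-DRB copies were chosen after the result was seen. The 6 replicates can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split called 134 genes and the highest other 0, so that 1 of 10 gave as many. The split of empty vector replicates 1 and 3 with NICD1 replicate 3 against the rest had 2388 genes at an unadjusted p under 0.05, against 2412 in the real split. For lists the real split called 15 and the highest other 15, so that 2 of 10 splits gave as many. Every other split called at least 5 lists, though each called 0 genes.

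NICD1 replicate 3 held the most NOTCH1 and lay farthest from the mean of the other NICD1 replicates, at 0.449 to 0.453 (root mean square log2 distance over 10 thinnings to the lowest total), with replicate 2 next at 0.375 to 0.378. After this thinning its distance from the mean of the others was at least 1.45 times the distance between them, which argues against depth as the cause. Admixed empty vector cells would dilute NOTCH1, whose log2 ratio to the higher of the other replicates was 1.66. This does not decide on admixture, because the amount of NICD1 per transduced cell was not measured and could differ between replicates. Of 14 Notch targets 11 (78.6%) were highest in replicate 3 among the NICD1 replicates, against 39.5% of all tested genes. HEYL, HES1, HES4, HEY1, NRARP and NOTCH3 were among the 11, whereas SOX9, JAG1 and CCND1 were lowest there. The 11 also include MYC and HES7, which there lay nearest the empty vector level, so the count alone does not show a stronger response. More NICD1 transcript may contribute as a hypothesis and cannot be told apart from another difference of this replicate, because a single replicate had that level.

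The rise of matrix genes could come from other cells or from a single replicate. Stellate cell and fibroblast markers moved with them, with a list median of 0.50 (adjusted p = 0.00326; adjusted p = 0.185 with an estimated correlation) and CYGB rising from 119 ± 5.43 to 213 ± 18.8 CPM. COL3A1, abundant in those cells, reached at most 0.0870 CPM in an NICD1 replicate while COL6A3 stood at 122 ± 33.6 CPM, which argues against such cells as the source of the matrix genes. Without NICD1 replicate 3 the 6 called matrix genes kept at least 0.858 of their log2 fold change, which argues against that replicate alone for these genes only, since calls favour genes high in every NICD1 replicate; the list median went from 0.15 to 0.07 (adjusted p = 0.00485), with 12 called higher and 6 lower. A response of the cells to NICD1 stays open as a hypothesis, as do differences between the samples that the labels do not describe.

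A set of 12 genes made of HLA class II genes, CD74 and their activator CIITA, chosen after the values were seen and not tested as a list, had 11 log2 fold changes below 0 and a median of -1.38. Of the set edgeR called only HLA-DRB5, and the antigen presentation list did not pass (adjusted p = 0.209, median 0.06) except in 4 of 18 alternatives (lowest 0.00217); HLA-DRA was at -2.65 (adjusted p = 0.157) and CIITA at -1.71 (adjusted p = 0.0605). Immune cells could carry these genes, but PTPRC reached at most 0.0942 CPM in an empty vector replicate, and CD74, which has no near-identical copy, was at -1.56 (adjusted p = 0.105), which argues against shared HLA-DRB reads alone. Without empty vector replicate 3, which held the highest level of each, the median was -1.04 and HLA-DRB5 was at -2.26 (adjusted p = 0.0584). This replicate thus adds to the size and does not account for all of it. HLA-DRB5 also did not pass without empty vector replicate 1 (adjusted p = 0.14), NICD1 replicate 1 (0.13) or NICD1 replicate 2 (0.139). Its lost call is not particular to empty vector replicate 3, and its adjusted p ran from 2.61e-18 to 0.215 over all alternatives. A lower class II programme with NICD1 stays open as a hypothesis.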
